A study of Mus musculus with 10 samples.

How the data were processed

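The series holds 10 arrays of total RNA from subcutaneous MC38 tumors of C57BL/6 mice, 5 injected with CpG1826 and 5 with PBS. Per the labels' protocols, RNA was extracted from the frozen tumors with a column kit and labelled with biotin by a whole-transcript amplification kit for Affymetrix arrays. The treatment protocol, worded alike for all 10 samples, describes the CpG1826 injection only, so the same schedule was assumed for the PBS mice. The deposited table holds 1 value per probe and array on a log2 scale, normalized between arrays by the authors as far as the values show. The log base was read from the values, which run from 2.03 to 14.70 as log2 of scanner intensities would. The submitters' processing notes name R 2.7.1 and limma with no role. Background correction, summarization and the normalization method are not given in the sources used here. The array medians lie close together and the sorted columns are not identical, so the distributions are alike without being equal. A normalization that makes the arrays' distributions alike can hide a shift shared by most genes, and the summarization of dim probes can compress their fold changes. Missing values, detection calls and background levels were not used here, so a low value is not called absent.

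The table has 35512 probes. Probe names came from the array's annotation table, which pairs 21789 probes with exactly 1 gene symbol, 1621 with several and 12102 with none. Only probes with exactly 1 symbol were used for genes, and 21698 of them matched a gene number in a RefSeq table for the assembly GRCm38.p6, used for names only, with 0 symbols changed. The remaining probes were not analysed in the gene tests. Where a gene had several probes (999 of 19938 genes), the probe with the highest mean over all arrays stood for it. Among called genes 33 had several probes, and for 2 of these the probes differed in sign. Genes without a probe of their own, among them Isg15, H2-K1, H2-D1 and Gbp2, were not analysed here. No coordinates are printed, because the genome build behind the table is not given in the sources used here.

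Each gene was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (default prior, two-sided), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. Fold changes are CpG1826 over PBS, and intervals are 95% confidence intervals of the moderated test. A second count added a log2 fold change of at least 1. Each array's title ends in its own number, read here as that of the mouse, and no number occurs in both groups, so nothing was blocked on. No batch, scan date or slide was used.

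The tests, the alternatives, the rule for named genes and 35 gene lists were set before the data were examined. The lists cover interferon, NF-κB, chemokine, cytokine, antigen presentation, sensor, checkpoint, feedback, acute phase, cell death, stress, hypoxia, cell cycle and metabolic genes, a comparison list of ribosomal proteins, and markers of the cell types that a subcutaneous tumor can hold. Each list was tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists, and members past the threshold were counted over all genes and over the list alone. A list's score in a tumor is the mean log2 value of its measured genes, and scores were compared with an exact permutation test of the 10 arrays (two-sided).

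The genes named were the 12 with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list with the largest change (or, where no member was called, the 2 with the highest level), and Tlr9, Myd88, Ifnb1, Ifng, Tnf, Il6, Il10, Il12b, Il1b, Cxcl10, Irf7, Cd274 and Nos2 whatever their values. This gave 109 genes. Other list members named beside them as examples, and genes outside the lists named in the closing section, were chosen after their values were seen.

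The alternatives were a further quantile normalization, median centring, leaving out genes below the median or below the lower quartile of level, a trended and robust prior, array weights, the mean of a gene's probes, all probes tested on their own, an adjusted p under 0.01, the limma treat test with a 1.5-fold minimum, camera with an estimated correlation, fry, and leaving out each mouse in turn. A fit with the keratinocyte list score of each array as a covariate was added after the data were seen, as were lists of hair follicle genes, further epidermal genes and abundant macrophage transcripts.

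The fit was tested on simulated data for this comparison with 19938 genes and 5 arrays per group. It recovered 72 of 100 genes changed by 0.5 log2 units and 98 of 100 changed by 1, with 10 unchanged genes among 188 calls. The T cell markers were raised as well and count among the changed genes. Noise was drawn independently for each gene, so these rates do not cover correlated genes. The median estimate was 0.984 of the true change. The number of arrays limits the precision, since the smallest two-sided p that a permutation of 5 against 5 can give is 0.00794.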

Results

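Gene expression was measured with whole-transcript arrays in subcutaneous tumors of MC38, a mouse colon carcinoma line, grown in C57BL/6 mice. Tumors of about 40 mm2 were injected with 50 µg of CpG1826 in 50 µL of PBS, and control tumors with PBS. CpG1826 is an oligodeoxynucleotide with unmethylated CpG motifs that activates mouse TLR9, an endosomal sensor of DNA. CpG1826 tumors were taken 6 h after the injection, and the same time was assumed for PBS tumors. Each array was taken as 1 mouse, named by the number in its title: 5 CpG1826 mice (50, 58, 183, 189 and 595) and 5 PBS mice (26, 29, 482, 592 and 661). The array medians lay between 6.47 and 6.53 on the log2 scale, and the number of arrays limits the precision of each value. Across probes, which are not independent replicates, pairs of arrays correlated at r = 0.980 to 0.994. The first principal component held 34.8% of the variance and separated the groups, and the second held 20.7%. The comparison asked which transcripts of the tumor differed within hours of a local TLR9 agonist.

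CpG1826 tumors had higher levels of transcripts for inflammatory mediators, innate effector proteins and skin keratins, and a smaller number of genes were lower. Lcn2, which encodes an iron-sequestering antibacterial protein, rose from 5.39 ± 0.21 to 9.56 ± 0.64 (SD, n = 5 per group), a log2 fold change of 4.17 ± 0.24 (SE) or 18.0-fold (95% confidence interval 12.6 to 25.8, limma with Benjamini-Hochberg adjustment, adjusted p = 4.95e-07). Il12b, the p40 subunit of IL-12 and IL-23, was 9.58-fold higher (6.88 to 13.3), and Nos2, the inducible nitric oxide synthase, 7.41-fold (5.49 to 10). The largest fall among genes whose groups did not overlap was that of Lair1, an inhibitory collagen receptor of leukocytes, from 8.78 ± 0.20 to 7.49 ± 0.40 (SD, n = 5 per group; 2.45-fold lower, 1.92 to 3.12, limma adjusted p = 0.000314). Cx3cr1, the fractalkine receptor of monocytes and macrophages, was 2.32-fold lower (1.92 to 2.79).

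Of 19938 genes tested, 930 (4.66%) passed the limma test at an adjusted p under 0.05, 710 of them higher and 220 lower in CpG1826 tumors. At least a 2-fold change was reached by 123 higher and 6 lower genes. The 5 CpG1826 values and the 5 PBS values did not overlap for 1351 genes, 6.78% of those tested, where chance gives 0.794%. The median log2 fold change over all genes was -0.02. The number of lower genes was the less stable count: it was 364 after a further quantile normalization, 338 with the genes below the median level left out, 144 without PBS mouse 29, 121 without PBS mouse 482, 137 without PBS mouse 592, 135 without CpG1826 mouse 50 and 142 without CpG1826 mouse 183. With the keratinocyte score described next as a covariate, 141 higher and 28 lower genes passed, 96 of them among the 930. In that fit 140 higher and 26 lower genes reached at least a 2-fold change. Its estimates are extrapolated and have wide errors, so these counts do not show larger effects.

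**Figure D1:**
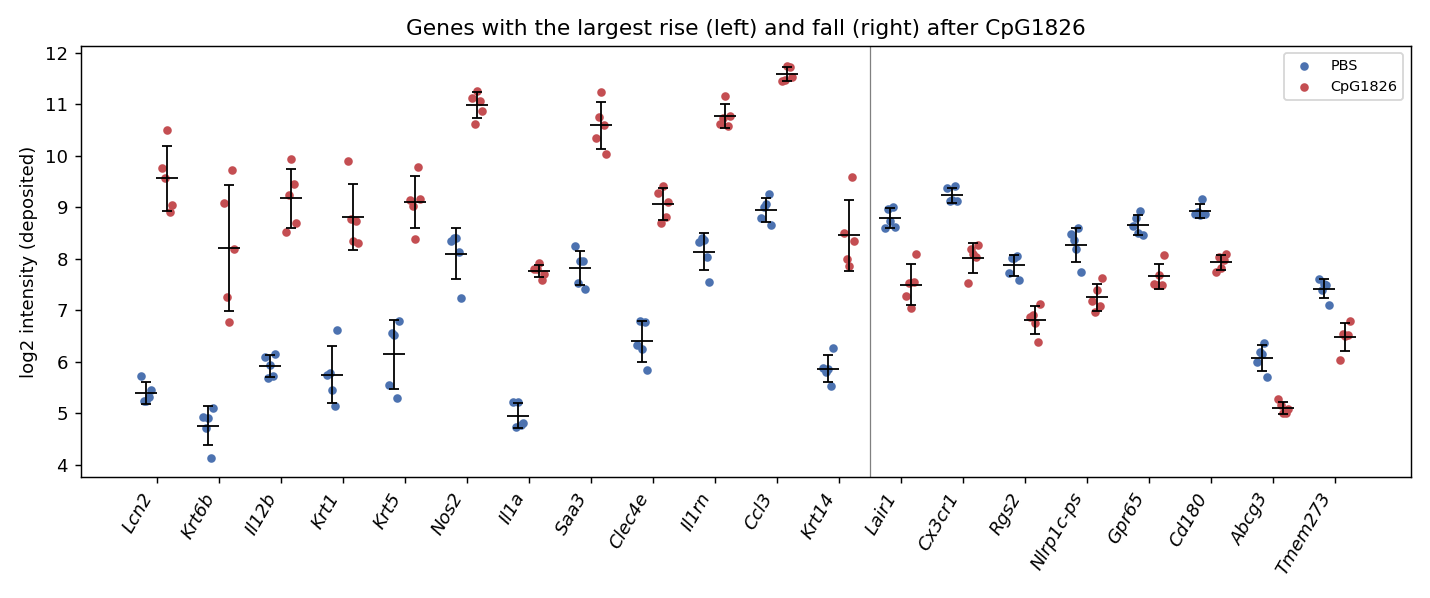
Deposited log2 intensity (vertical axis) of the 12 genes with the largest rise and the 8 genes with the largest fall among called genes whose groups did not overlap (horizontal axis), with 1 point per tumor, 5 PBS (blue) and 5 CpG1826 (red), the mean as a horizontal bar and the SD as whiskers. Lcn2 lay at 5.39 in PBS and 9.56 in CpG1826 tumors on average, and Lair1 at 8.78 and 7.49.

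Transcripts of skin keratinocytes differed most among the cell type markers. Of 18 measured keratinocyte markers, 13 rose and 0 fell (16 and 0 when adjusted over the list alone), with a median log2 fold change of 1.51. Krt1 and Krt5, keratins of the upper and the basal epidermis, were 8.35-fold (5.33 to 13.1) and 7.75-fold (4.97 to 12.1) higher, Krt14, the partner of Krt5, 6.05-fold (4.09 to 8.94), and Krtdap 5.28-fold (4.37 to 6.37). Outside the list, Krt6b, a keratin of wounded epidermis, was 10.9-fold higher (5.57 to 21.4) with an SD of 1.23 between the CpG1826 tumors. Trp63, Krt15 and Ivl did not pass (log2 fold changes of 0.25, 0.26 and 0.17). The mean log2 level of the list, its score, was 5.58 ± 0.18 in PBS and 7.04 ± 0.31 in CpG1826 tumors (SD, n = 5 per group, exact permutation test, two-sided p = 0.00794, the smallest that 5 against 5 can give, adjusted p = 0.0198). This score was higher in 5 of 5 CpG1826 tumors than in any PBS tumor. In the limma camera test, the list's adjusted p was 2.60e-29 with the preset correlation and adjusted p = 0.0116 with an estimated correlation. The score and the group were nearly collinear (r = 0.956). A fit with the score as a covariate, chosen after the data were seen, therefore stands beside most of the gene groups that follow. The score was at most 5.81 in PBS and at least 6.67 in CpG1826 tumors, so values from that fit are extrapolated. The score may itself be changed by the treatment. Such values are therefore not effects that remain once skin is removed.

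NF-κB target genes rose nearly as a whole. Of 31 measured immediate targets, 29 rose and 0 fell, the same counts as when adjusted over the list alone, with a median log2 fold change of 0.67. Il1a was 7.04-fold higher (6.00 to 8.26), Tnip3, an inhibitor of NF-κB signalling, 5.41-fold (4.63 to 6.34), Il1b 4.85-fold (3.91 to 6.02) and Gadd45b 2.66-fold (2.28 to 3.10). Cxcl2, a neutrophil attractant, rose 3.84-fold (2.65 to 5.57). Tnf rose by 0.86 ± 0.10 and Il6 by 1.15 ± 0.15 on the log2 scale (SE), and Sele and Ccl20 did not pass (-0.06 and -0.03). The list score was 8.27 ± 0.06 in PBS and 9.18 ± 0.11 in CpG1826 tumors (SD, n = 5 per group; exact permutation test, adjusted p = 0.0198). The limma camera adjusted p was 3.56e-50, and adjusted p = 0.0116 with an estimated correlation. With the keratinocyte score, itself 1.45 higher in the CpG1826 tumors, as a covariate, 8 of the 31 genes passed, at a median log2 fold change of 0.92.

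Inhibitors that limit cytokine and TLR signals rose in most members, and cytokines in part. Of 21 measured feedback inhibitors, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.95. Il1rn, the interleukin-1 receptor antagonist, was 6.24-fold higher (4.92 to 7.90), Il10, an anti-inflammatory cytokine, 5.54-fold (3.88 to 7.91), Dusp1, a MAP kinase phosphatase, 3.33-fold (2.82 to 3.93) and Irak3, an inhibitory member of the IRAK family, 2.23-fold (1.78 to 2.79). Of the 21 genes, 12 are also on another list. Among 38 measured cytokines, 11 rose and 2 fell (12 and 2 adjusted over the list alone), and the median log2 fold change of 0.09 lay below the mean of 0.51; without CpG1826 mouse 189 the median was 0.06. Ebi3 (1.21), Il27 (0.98) and Il15 (0.79) rose, Tgfb3 fell by 0.68 and Tnfsf13b by 0.47 on the log2 scale. The limma camera test gave an adjusted p of 1.04e-26 for the inhibitors and 3.76e-09 for the cytokines, and adjusted p = 0.0116 and adjusted p = 0.0139 with an estimated correlation. In the fit with the keratinocyte covariate, 8 inhibitors and 5 cytokines passed, at medians of 0.98 and -0.05.

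Chemokine genes rose in part. Of 34 measured chemokines, 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.27. Ccl3 and Ccl4 were 6.21-fold (5.28 to 7.31) and 4.34-fold (3.81 to 4.95) higher, and Cxcl3 2.76-fold (2.14 to 3.56). Ccl2 and Ccl7, ligands of the monocyte receptor CCR2, rose by 0.77 and 0.66 on the log2 scale, while Ccl22 did not pass (0.26). The limma camera adjusted p was 8.99e-13, and adjusted p = 0.0116 with an estimated correlation. Beside the keratinocyte covariate, 2 of the 34 chemokines passed, at a median of 0.29, with Ccl3 at 2.95, Ccl4 at 2.27, Cxcl11 at 1.29 and Cxcl3 at 0.84. The list kept its camera call at the preset correlation, a weak criterion, since other groupings of the arrays passed up to 23 lists. Those groupings mix CpG1826 and PBS arrays, so they are not free of the treatment.

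Acute phase and innate effector genes contained the largest single rise. Of 24 measured members, 13 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 0.57. Besides Lcn2, Saa3, an acute phase protein, was 6.83-fold higher (5.04 to 9.25), Clec4e, a receptor for mycobacterial cord factor, 6.36-fold (4.85 to 8.34) and Acod1, which makes itaconate, 3.75-fold (2.78 to 5.05). The limma camera adjusted p was 2.59e-20, and adjusted p = 0.0116 with an estimated correlation. With the keratinocyte covariate 4 of the 24 genes passed, at a median of 1.32. Lcn2 was at 5.82, Saa3 at 4.03, Clec4e at 3.64 and Acod1 (not past the threshold) at 2.35. The list kept its camera call at the preset correlation, with the same weakness as for the chemokines.

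Interferon-stimulated genes rose, the largest by 1.27 on the log2 scale, below the largest rise of each list above it. Interferon genes themselves, most of them at low levels, did not pass the test. Of 37 measured type I interferon-stimulated genes, 22 rose and 0 fell (35 and 0 adjusted over the list alone), with a median log2 fold change of 0.45. Mx2 was 2.41-fold higher (1.99 to 2.91), Rsad2 2.06-fold (1.75 to 2.43), Mx1 1.89-fold (1.6 to 2.23) and Cmpk2 1.88-fold (1.58 to 2.25). Irf7, the transcription factor of the interferon feedback loop, did not pass (0.36 ± 0.11, limma adjusted p = 0.0959), and it passed without CpG1826 mouse 50 (0.45, limma adjusted p = 0.0217; 0.0217 to 0.216 over the fits that leave out 1 mouse), with a trended, robust prior (limma adjusted p = 0.0462) and with the genes below the median level left out (limma adjusted p = 0.0494). The list score was 9.65 ± 0.18 in PBS and 10.16 ± 0.15 in CpG1826 tumors (SD, n = 5 per group, exact permutation test, adjusted p = 0.0198). By limma camera the list had an adjusted p of 9.18e-33, but adjusted p = 0.0939 with an estimated correlation. The number that rose was 13 without PBS mouse 26, 14 without PBS mouse 29, 13 without PBS mouse 661, and 14 without CpG1826 mouse 58 or 595. In the fit with the keratinocyte covariate, 0 of these genes passed, at a median log2 fold change of 0.83.

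Among 14 measured type I and III interferon genes, 0 passed the limma test in either direction, also when adjusted over the list alone, and 1 was higher and 2 were lower at an unadjusted p under 0.05. Their median log2 fold change was -0.01 and their mean 0.00 (limma camera adjusted p = 0.721). Only 3 of the 14 lay above the median gene level in PBS tumors, and their median PBS level was 4.88, so a rise could be missed. Ifna1, Ifna6, Ifna7 and Ifnl3 had no probe of their own and were not tested. Ifnb1 differed by 0.19 ± 0.10 (95% confidence interval -0.02 to 0.39, limma adjusted p = 0.382), Ifnz by -0.17 ± 0.08 and Ifnl2 by -0.17 ± 0.13 (SE). Ifng differed by -0.03 ± 0.15 (-0.35 to 0.29, limma adjusted p = 0.955). Of 21 measured genes inducible by interferon-γ, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.26 that was 0.17 without PBS mouse 661. Besides Nos2, the members that rose were Cd274, which encodes the checkpoint ligand PD-L1 (2.54-fold, 1.97 to 3.27), Cxcl11 (2.07-fold, 1.68 to 2.54), Gbp5 (2.05-fold, 1.68 to 2.51), Fcgr4 (0.65 on the log2 scale) and Cxcl10 (1.38-fold, 1.21 to 1.57). Ciita, the master regulator of MHC class II genes, was 1.78-fold lower (1.43 to 2.22). The limma camera adjusted p of this list was 6.14e-11, and adjusted p = 0.225 with an estimated correlation; 1 gene passed with the keratinocyte covariate, at a median of 0.51.

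Genes of MHC class I presentation did not pass: of 18 measured, 0 passed the limma test, also when adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05 (median log2 fold change 0.04, limma camera adjusted p = 0.102). The camera call for class I was gained without PBS mouse 29 (adjusted p = 0.0493), PBS mouse 592 (adjusted p = 0.0388) or CpG1826 mouse 50 (adjusted p = 0.0194). B2m and Canx differed by -0.03 ± 0.07 and -0.08 ± 0.06 (SE). Of 12 measured class II genes, 2 fell, Ciita and H2-DMa, a chaperone of peptide loading (1.56-fold lower, 1.34 to 1.80), and 0 rose, the same counts as when adjusted over the list alone. H2-Ab1, H2-Aa and Cd74 did not pass (-0.13, -0.14 and -0.05). The class II median was -0.13, and -0.24 without PBS mouse 661 (limma camera adjusted p = 0.00445, and adjusted p = 0.395 with an estimated correlation), and its camera call was lost with the genes below the median level left out (adjusted p = 0.0998). In the fit with the covariate 0 class II genes passed, at a median of 0.47, while Ciita and H2-DMa lost their calls but stayed lower.

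Tlr9 itself, the receptor of CpG1826, did not pass (-0.24 ± 0.09, limma adjusted p = 0.211), nor did its adaptor Myd88 (0.16 ± 0.08, limma adjusted p = 0.320). Of 28 measured genes of the TLR9 pathway and related sensors, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 fold change of 0.10 that was 0.06 without CpG1826 mouse 595. Cd14, a co-receptor of several TLRs, was 4.33-fold higher (3.45 to 5.44), Nlrp3, an inflammasome sensor, 1.5-fold (1.27 to 1.78), and Irak3, Tlr2 (0.57) and Irak2 (0.35) also rose. Tlr13, a sensor of bacterial ribosomal RNA, was 1.52-fold lower (1.25 to 1.85), a call lost without PBS mouse 29 (limma adjusted p = 0.0511; 0.0177 to 0.0511 over the fits that leave out 1 mouse). This list had a limma camera adjusted p of 0.000397, and adjusted p = 0.395 with an estimated correlation. In the fit with the keratinocyte covariate, 5 of the 28 genes passed, at a median of 0.52.

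Costimulatory ligands and checkpoint genes moved in both directions. Of 24 measured, 5 rose and 2 fell (8 and 2 adjusted over the list alone). Tnfrsf9, which encodes 4-1BB, was 2.71-fold higher (2.20 to 3.33), Cd40 2.40-fold (2.01 to 2.88) and Tnfsf9, the 4-1BB ligand, 1.93-fold (1.65 to 2.25), and Cd274 and Cd80 (0.57) also rose. Icosl fell by 0.55 and Sirpa by 0.39 on the log2 scale, and the count that fell was 1 without PBS mouse 29. The median of 0.19 was 0.08 without PBS mouse 661 and 0.13 without CpG1826 mouse 183 (limma camera adjusted p = 7.84e-05, and adjusted p = 0.395 with an estimated correlation). Beside the keratinocyte covariate, 3 of the 24 genes passed, at a median of 1.06. Cd274 was at 1.77, Cd40 at 1.71 and Tnfsf9 at 1.41 (none of the 3 past the threshold). The list kept its camera call at the preset correlation, with the same weakness as for the chemokines.

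Genes of cell death, stress and hypoxia rose in part. Among 21 cell death genes, Fas (2.17-fold, 1.80 to 2.61), Casp4 (1.84-fold, 1.62 to 2.10), Daxx (1.48-fold, 1.22 to 1.79) and Tnfrsf10b (1.30-fold, 1.17 to 1.44) rose and 0 fell (6 and 0 adjusted over the list alone). The Daxx call was lost without PBS mouse 26, 29 or 661 or CpG1826 mouse 189 or 595 (limma adjusted p = 0.00817 to 0.0626 over the fits that leave out 1 mouse). Of 24 immediate early and stress genes, 7 rose and 0 fell (12 and 0 adjusted over the list alone), among them Atf3 (1.94-fold, 1.42 to 2.66), a call lost without PBS mouse 26 (limma adjusted p = 0.0582; 0.00623 to 0.0582 over such fits), and Gadd45a (1.61-fold, 1.30 to 1.98). Fos (0.18) and Myc (0.22) did not pass. Of 24 genes of hypoxia and glycolysis, 9 rose and 0 fell (13 and 0 adjusted over the list alone): Pfkfb3, a regulator of glycolytic flux, was 3.46-fold higher (2.81 to 4.27), Ndrg1 1.79-fold (1.59 to 2.03), Adm 1.78-fold (1.45 to 2.19) and the glucose transporter Slc2a1 1.62-fold (1.42 to 1.84). These 3 lists had medians of 0.20, 0.31 and 0.22. Their limma camera adjusted p values were 6.06e-08, 1.99e-11 and 2.66e-14, and with an estimated correlation adjusted p = 0.110, adjusted p = 0.112 and adjusted p = 0.0726. With the keratinocyte covariate 0, 2 and 1 of their genes passed, at medians of 0.48, -0.24 and -0.24.

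Cell cycle genes were slightly lower. Of 34 measured, 5 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 fold change of -0.17. Cdc6, which loads the replicative helicase, was 1.38-fold lower (1.21 to 1.57), Pcna, the sliding clamp of DNA replication, 1.25-fold (1.14 to 1.37), Mcm5 1.21-fold (1.10 to 1.34) and Cenpa 1.19-fold (1.08 to 1.31), and Mcm3 fell by 0.25 on the log2 scale. Mki67 and Top2a did not pass (-0.11 and -0.14). The count that fell was 3 without PBS mouse 29 or 661 or CpG1826 mouse 183 or 189, and 2 without PBS mouse 482 or 592 or CpG1826 mouse 595. The calls of Mcm5 and Cenpa were among those lost, Mcm5 without PBS mouse 482 or 592 or CpG1826 mouse 595 (limma adjusted p of 0.0279 to 0.0693 over the fits that leave out 1 mouse), and Cenpa in 8 of the 10 such fits, all but those without PBS mouse 26 and CpG1826 mouse 58 (0.0326 to 0.112). Cenpa was also lost after median centring (limma adjusted p = 0.0639). As a list they had a limma camera adjusted p of 1.91e-09, and adjusted p = 0.242 with an estimated correlation. Beside the covariate 0 cell cycle genes passed, at a median of 0.03.

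Metabolic and reference lists moved little. Of 18 genes of cholesterol synthesis and uptake, Stard4 fell (1.25-fold lower, 1.11 to 1.41) and 0 rose (1 and 0 adjusted over the list alone); the call was kept only without PBS mouse 26 or 29 or CpG1826 mouse 595 (limma adjusted p of 0.0383 to 0.0949 over the fits that leave out 1 mouse). The median of -0.12 was -0.07 without CpG1826 mouse 183, where the camera call was lost (limma camera adjusted p = 0.0739 against 0.00216, and adjusted p = 0.619 with an estimated correlation); beside the keratinocyte covariate the median was -0.62 and 0 genes passed. Of 28 oxidative phosphorylation genes 0 passed the limma test, also when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (median -0.05, limma camera adjusted p = 0.102), with Atp5b at -0.06 ± 0.06 and Atp5a1 at -0.11 ± 0.06 (SE). Its camera call was gained without PBS mouse 26 (adjusted p = 0.0131), PBS mouse 661 (adjusted p = 0.0446) or CpG1826 mouse 58 (adjusted p = 0.0255) or 595 (adjusted p = 0.0459), and after a further quantile normalization (adjusted p = 0.0198). Of 23 ribosomal protein genes 0 passed, with 0 at an unadjusted p under 0.05, and the list score differed by 0.02 (95% confidence interval -0.05 to 0.097), with Rplp0 at 0.02 and Rpl10 at 0.01.

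**Figure D2:**
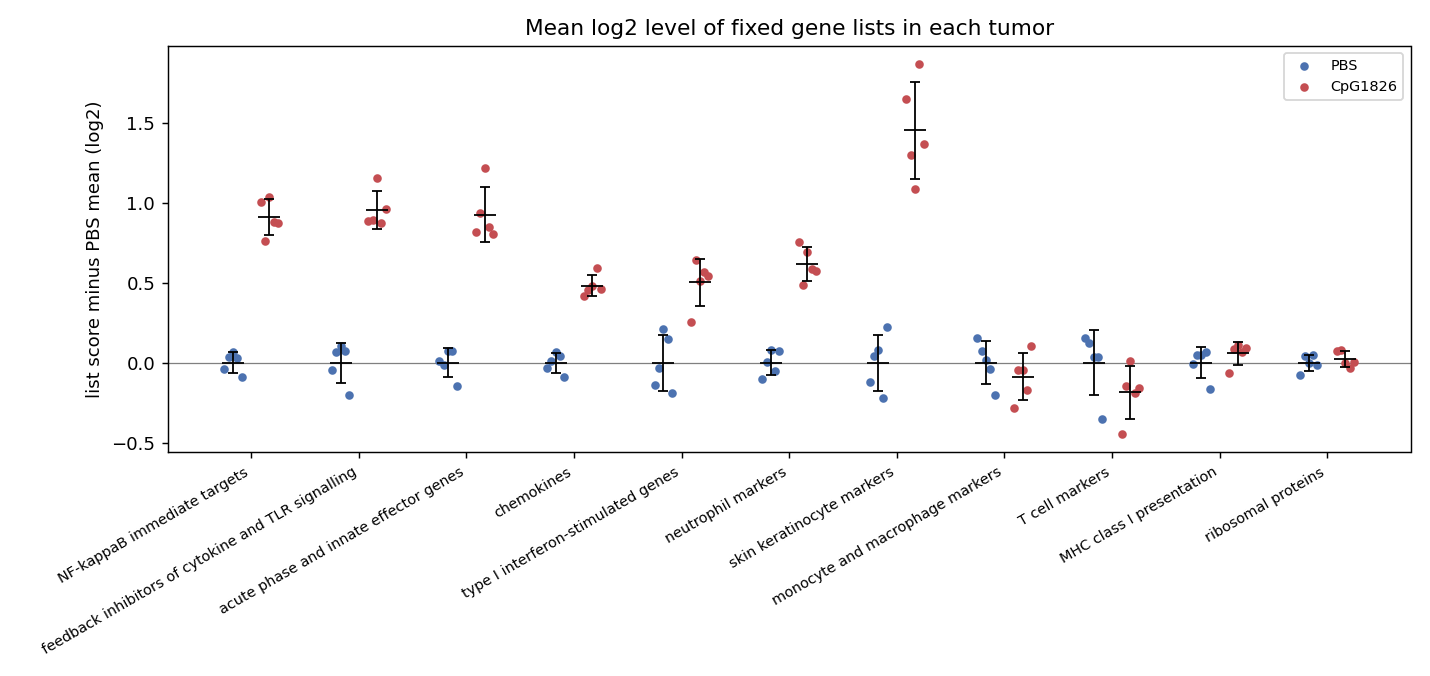
Score of 11 fixed gene lists (horizontal axis) in each tumor, as the mean log2 level of the list's genes minus its mean over the PBS tumors (vertical axis), with 1 point per tumor, 5 PBS (blue) and 5 CpG1826 (red), the mean as a horizontal bar and the SD as whiskers. The keratinocyte score was 1.45 higher on average in CpG1826 tumors, the NF-κB score 0.91 higher and the ribosomal protein score 0.02 higher.

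Neutrophil markers rose in part. Of 19 measured, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.59. S100a8 and S100a9, the subunits of calprotectin, were 4.37-fold (3.11 to 6.13) and 2.74-fold (2.09 to 3.58) higher, Cxcr2, the receptor of Cxcl2, 3.11-fold (2.36 to 4.10) and Hdc, the enzyme that makes histamine, 3.06-fold (2.48 to 3.77). Ly6g, Mpo and Elane did not pass (0.00, 0.02 and -0.03), and their PBS means lay between 4.70 and 5.34. The limma camera adjusted p was 1.25e-11, and adjusted p = 0.0116 with an estimated correlation. With the keratinocyte covariate 1 of the 19 genes passed, at a median of 0.58. S100a8 was at 1.37, Hdc at 1.32, Cxcr2 at 1.27 and S100a9 at 0.58 (none of the 4 past the threshold). The list kept its camera call at the preset correlation, with the same weakness as for the chemokines.

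Among monocyte and macrophage markers, 2 of 21 rose and 3 fell (4 and 3 adjusted over the list alone), and the list as a whole did not shift (median -0.12, limma camera adjusted p = 0.644). Msr1, a scavenger receptor, was 1.58-fold higher (1.38 to 1.81) and Fcgr1 rose by 0.40. Cx3cr1 fell, as did Csf1r, the receptor of macrophage growth factor CSF1 (1.37-fold lower, 1.19 to 1.58), and Ccr2 (1.53-fold lower, 1.20 to 1.95). The abundant transcripts Lyz2, Cd68, C1qa and Adgre1 did not pass (-0.09, -0.02, -0.14 and 0.03). The Ccr2 call was kept only without CpG1826 mouse 595 among the fits that leave out 1 mouse (limma adjusted p = 0.0158 to 0.127). The count that rose was 1 without PBS mouse 26, 482 or 661 or CpG1826 mouse 58, 183 or 595. Beside the keratinocyte covariate, 1 marker rose and 0 fell, at a median of 0.56. Besides Lair1 and Cx3cr1, the genes with the largest falls were Rgs2 (2.10-fold lower, 1.73 to 2.56), Nlrp1c-ps (2.03-fold, 1.61 to 2.56), Gpr65, a proton-sensing receptor of leukocytes (2.0-fold, 1.67 to 2.41), Cd180, a TLR4-related receptor (2.0-fold, 1.76 to 2.27), Abcg3 (1.97-fold, 1.67 to 2.32) and Tmem273 (1.92-fold, 1.59 to 2.32). All 8 lost their call beside the covariate, with log2 fold changes of -1.36 for Lair1, -0.47 for Cx3cr1, -0.33 for Rgs2, -0.03 for Nlrp1c-ps, -0.34 for Gpr65, -0.78 for Cd180, -0.67 for Abcg3 and -0.29 for Tmem273.

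Dendritic cell markers changed in few members. Of 11 plasmacytoid dendritic cell markers, Ly6d (2.88-fold, 1.98 to 4.18) and Spib (1.78-fold, 1.38 to 2.28) rose and 0 fell (2 and 1 adjusted over the list alone). Ly6d was -0.77 and Spib 1.10 with the keratinocyte covariate, where 0 of these markers passed. Siglech did not pass (-0.04), and the median of -0.02 was opposite in sign to the mean of 0.17 (limma camera, upwards, adjusted p = 0.465; exact permutation test of the score, adjusted p = 0.0198). Of 14 conventional dendritic cell markers, Cd83 (1.70-fold, 1.44 to 2.0) and Ccr7 (1.69-fold, 1.36 to 2.09), genes of mature dendritic cells, rose and 0 fell (2 and 2 adjusted over the list alone), with a median of -0.08, a mean of 0.05 and a camera direction upwards (limma camera adjusted p = 0.791); with the genes below the median level left out, the median was 0.30 and the list passed (limma camera adjusted p = 0.0227). Without CpG1826 mouse 189, 2 of the conventional dendritic cell markers fell. With the keratinocyte covariate 0 of them passed, at a median of -0.03.

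Lymphocyte markers mostly did not pass. Of 14 B cell markers 0 passed the limma test, also when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (median -0.07, limma camera adjusted p = 0.348), with Cd37 at -0.01 ± 0.10 and Blnk at 0.16 ± 0.15 (SE). Of 15 T cell markers 0 passed the limma test, also when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Cd3g differed by -0.51 ± 0.25 and Cd8a by -0.29 ± 0.18 (SE). The T cell median was -0.11, and -0.20 without PBS mouse 661 and -0.17 without CpG1826 mouse 189. The T cell list passed the limma camera test downwards (adjusted p = 0.0102, and adjusted p = 0.606 with an estimated correlation), a call lost without PBS mouse 26 (adjusted p = 0.0789) and reversed to upwards beside the keratinocyte covariate (median 0.17). Of 20 NK and cytotoxic cell markers, Gzmb, the cytotoxic protease granzyme B (2.23-fold, 1.65 to 3.01), and Ccl5 (1.91-fold, 1.59 to 2.31) rose and 0 fell (3 and 0 adjusted over the list alone), and Ncr1 did not pass (-0.22). The median of -0.04 was opposite in sign to the mean of 0.11 (limma camera, upwards, adjusted p = 0.246), and the camera call was gained without CpG1826 mouse 50 (adjusted p = 0.00908) or with the genes below the median level left out (adjusted p = 0.0156). Beside the covariate 1 NK marker passed, at a median of 1.66. Of 14 mast cell and basophil markers Hdc alone rose and 0 fell (1 and 0 adjusted over the list alone; median 0.09, limma camera adjusted p = 0.0569), with the camera call gained without PBS mouse 29 (adjusted p = 0.00648), PBS mouse 482 (adjusted p = 0.00645) or CpG1826 mouse 50 (adjusted p = 0.00924), after a further quantile normalization (adjusted p = 0.0446) or with the genes below the lower quartile of level left out (adjusted p = 0.0263).

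Stromal and other tissue markers showed few changes. Of 16 fibroblast markers 0 passed the limma test (0 higher and 1 lower adjusted over the list alone), and 4 were lower at an unadjusted p under 0.05 (median -0.09, limma camera adjusted p = 0.174), with Dcn at 0.09 ± 0.08 and Col1a1 at -0.28 ± 0.11 (SE). The camera call was gained downwards without CpG1826 mouse 58 (adjusted p = 0.0270). Of 19 endothelial markers Aplnr (1.32-fold lower, 1.13 to 1.54) and Tek (1.27-fold lower, 1.11 to 1.45) fell and 0 rose (3 lower and 1 higher adjusted over the list alone; median -0.06, limma camera adjusted p = 0.326). Among the fits that leave out 1 mouse, the Aplnr call was kept only without PBS mouse 29 or CpG1826 mouse 189 (limma adjusted p of 0.0187 to 0.107), and the Tek call only without PBS mouse 29 or 592 (0.0390 to 0.117). Aplnr was also lost with array weights (limma adjusted p = 0.0599) and Tek with a trended, robust variance prior (limma adjusted p = 0.0592). Both lost their call beside the keratinocyte covariate, where the camera direction of the endothelial list reversed to upwards. Of 14 pericyte and smooth muscle markers 0 passed, also when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (median -0.10, limma camera adjusted p = 0.644), with Acta2 at 0.17 ± 0.11 and Mcam at -0.18 ± 0.11 (SE). Of 20 skeletal muscle markers 0 passed, also when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05, with Acta1 at -0.25 ± 0.21 and Tnnt3 at -0.34 ± 0.15 (SE). Tnnt3 passed without CpG1826 mouse 183 (limma adjusted p = 0.0316; 0.0316 to 0.480 over such fits). The muscle median was -0.16, and -0.33 without CpG1826 mouse 183 (limma camera downwards, adjusted p = 0.00787, and adjusted p = 0.700 with an estimated correlation), and the camera call was lost without PBS mouse 29 (adjusted p = 0.103) or CpG1826 mouse 189 (adjusted p = 0.212) and reversed to upwards beside the keratinocyte covariate (median 0.76).

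Of 17 epithelial and colon carcinoma markers, Cdh1 (1.55-fold, 1.28 to 1.87), Esrp1 (1.43-fold, 1.22 to 1.67) and Epcam (1.25-fold, 1.10 to 1.42) rose and 0 fell (3 and 0 adjusted over the list alone; median 0.03, limma camera adjusted p = 0.174). With the keratinocyte covariate 0 of these markers passed, with Cdh1 at 0.10, Esrp1 at 0.12 and Epcam at -0.24. Krt8 and Krt18 did not pass (0.12 and -0.11). The Epcam call was kept only without PBS mouse 26 or CpG1826 mouse 183 among the fits that leave out 1 mouse (limma adjusted p of 0.0283 to 0.126), and lost with a trended, robust variance prior (limma adjusted p = 0.0648). Of 14 adipocyte markers 0 passed, also when adjusted over the list alone, and 1 was higher and 2 were lower at an unadjusted p under 0.05 (median -0.01, limma camera adjusted p = 0.732), with Pnpla2 at 0.22 ± 0.08 and Scd1 at -0.06 ± 0.11 (SE). Of 7 erythroid and platelet markers 0 passed, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 (median -0.01, limma camera adjusted p = 0.721), and Pf4 differed by 0.11 ± 0.15 and Itga2b by -0.09 ± 0.08 (SE).

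**Figure D3:**
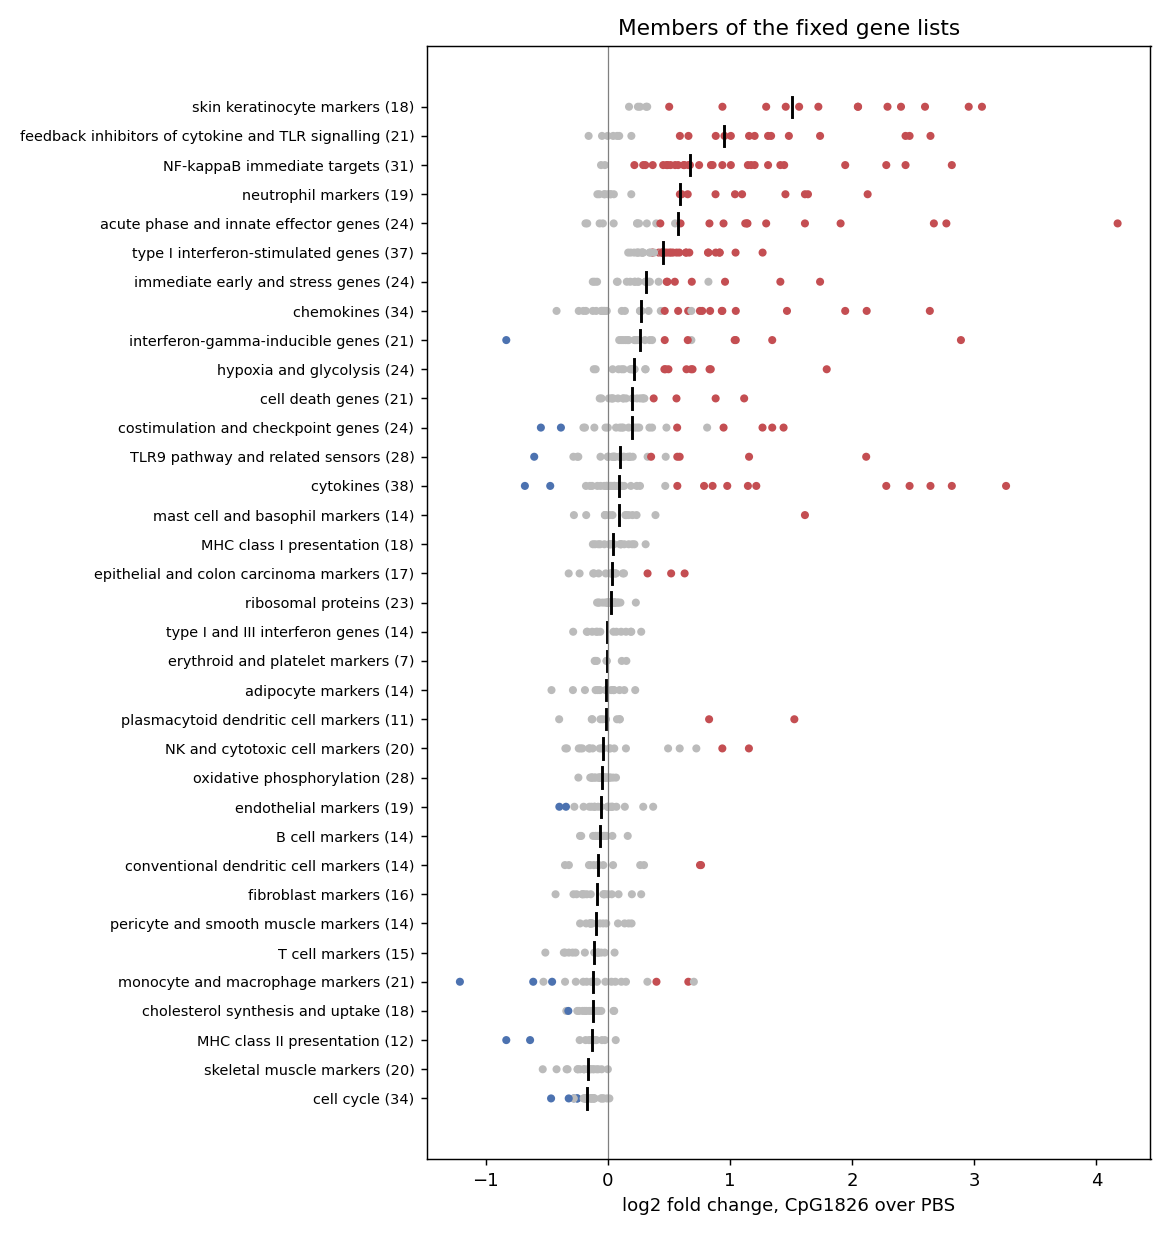
Log2 fold change, CpG1826 over PBS (horizontal axis), of each measured gene of the 35 fixed lists (vertical axis, number of genes in parentheses), with red for genes that rose, blue for genes that fell, grey for genes that did not pass the limma test, and a black bar at the list's median. Medians ran from -0.17 for cell cycle genes to 1.51 for keratinocyte markers.

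By the limma camera test 19 of the 35 lists passed, 14 upwards and 5 downwards, but other groupings of the same 10 arrays passed up to 23 lists. Those groupings mix CpG1826 and PBS arrays, so they are not free of the treatment. With a correlation estimated for each list, 7 passed: NF-κB targets, feedback inhibitors, acute phase genes, chemokines, cytokines, neutrophil markers and keratinocyte markers. These are not 7 independent results, since lists share genes. On another list too were 13 of 31 NF-κB targets, 12 of 21 feedback inhibitors, 11 of 34 chemokines and 8 of 38 cytokines. In the exact permutation test of the scores, 15 lists passed after adjustment over the 35 lists.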

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

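The tests of hair follicle genes (also without mouse 58), array scale, macrophage number and dilution, and the fit with the keratinocyte covariate, were chosen after the results they bear on had been seen, and the test of further epidermal genes after the main comparison but before its own value.

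Of 288 sets of 5 values checked, 27 held a tumor far from the other 4, where chance alone gives about 14.4 (1 in 20 sets). PBS mouse 661 lay low in the score of costimulation and checkpoint genes (7.31, others 7.67 to 7.78), the T cell marker score (6.69, others 7.08 to 7.20), Nos2 (7.23, others 8.13 to 8.40), Tnfsf9 (6.22, others 6.38 to 6.44), Fas (6.95, others 7.38 to 7.53), Blnk (6.57, others 7.12 to 7.34), Cd3g (7.86, others 8.73 to 8.99) and Cd8a (7.76, others 8.44 to 8.63). PBS mouse 26 lay high in Adm (8.07, others 7.82 to 7.87), Cdc6 (8.89, others 8.52 to 8.59) and Ccr7 (7.51, others 6.68 to 6.92), and low in Rplp0 (13.12, others 13.21 to 13.24), Scd1 (9.80, others 10.16 to 10.29) and Pnpla2 (7.27, others 7.46 to 7.53). CpG1826 mouse 50 lay high in the score of immediate early and stress genes (9.22, others 8.74 to 8.87), Cxcl2 (8.51, others 6.96 to 7.06), Atf3 (9.75, others 8.65 to 8.93) and S100a9 (8.01, others 7.02 to 7.26), and low in the MHC class I score (10.59, others 10.72 to 10.76) and Gbp5 (9.74, others 10.05 to 10.16). CpG1826 mouse 183 lay high in the pericyte score (6.98, others 6.66 to 6.73), Irak3 (8.86, others 8.06 to 8.24), Pfkfb3 (10.97, others 10.27 to 10.47) and Pnpla2 (7.87, others 7.59 to 7.65), and low in Stard4 (7.74, others 8.0 to 8.11). The B cell score was high in PBS mouse 482 (5.68, others 5.50 to 5.55), and Cd180 in PBS mouse 592 (9.16, others 8.85 to 8.90). Among the 12102 probes with no gene name here, which no comparison of genes used, 49 were higher and 14 lower in CpG1826 tumors.

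Chance is argued against for the counts of genes. Of 100 splits of the 10 arrays into 5 and 5, the real one included, 1 gave as many called genes as the real split (930, against 1 in the highest of the others), and 1 gave as many genes changed at least 2-fold (129, against 0). The other splits mix CpG1826 and PBS arrays, which widens the spread of changed genes and lowers these counts. For the number of lists that passed camera at its preset correlation, 16 of the 100 splits gave at least as many as the real one (19, against 23 in the highest of the others). The other splits hold unequal shares of CpG1826 arrays and can keep part of the difference between the groups. They are therefore no null free of the treatment and cannot decide this count, and chance is not excluded for it.

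Keratinocyte markers were higher in every CpG1826 tumor, with Krt5 at 9.10, Krt1 at 8.81 and Krt14 at 8.45 on average. Only 1 of the 18 list genes lay above the median gene level in PBS tumors, 0 are on another list, and the labels name no sort that would remove skin. Skin carried along with the tumor is a candidate source, and so is a rise of these genes in cells of the tumor or its cover after CpG1826. The hair follicle score differed by 0.234 (95% confidence interval -0.566 to 1.034), an interval that holds 0.727, that is 0.5 of the keratinocyte rise, but through CpG1826 mouse 58 alone (6.85): without it the difference was -0.097 (-0.373 to 0.179), below 0.747, which argues against skin with growing follicles in the other 4 tumors and leaves skin without them open. Of 32 measured further epidermal genes 31.2% passed upwards (10 genes; score difference 0.40, 95% confidence interval 0.17 to 0.62), the list as a whole passed the limma camera test, and the share lies between the bounds of 30% and 60% that would have argued against and for more epidermal cells, so epidermal RNA and the treatment cannot be told apart.

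NF-κB targets were higher in every CpG1826 tumor. RNA of epidermal cells is argued against as the whole cause: with the keratinocyte score as a covariate, the NF-κB score still differed by 0.999 (0.508 to 1.491), against 0.91 without it, and the lower bound lies above 0.456, that is 0.5 of the value without it. In the fits that leave out 1 mouse the lower bound with the covariate stayed above 0 (0.164 to 0.744). It fell below 0.5 of the rise without PBS mouse 592 (0.425) or 661 (0.336) or CpG1826 mouse 183 (0.164) or 189 (0.323). The score is also nearly collinear with the group (r = 0.956), so this fit cannot decide. RNA of epidermal cells therefore stays open as a cause. A scale difference between the groups' arrays is argued against, since the score still differed by 0.898 (0.743 to 1.052) after a further quantile normalization. As a hypothesis found and tested on the same data, the rise may reflect a response of cells in the tumor to CpG1826, or neutrophils that arrived. No test here separates these. The neutrophil marker score was 0.62 higher (0.48 to 0.75) and 10 of 19 markers rose, but Ly6g, Mpo and Elane, at low levels, did not pass.

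Cx3cr1, Csf1r and Ccr2 were lower in CpG1826 tumors, with a median log2 fold change of -0.61. A loss of macrophages by 0.5 of that median fall or more is argued against. The score of 14 abundant macrophage transcripts differed by -0.025 (-0.257 to 0.207), above the bound of -0.31, that is 0.5 of the fall. Without CpG1826 mouse 183, though, the lower limit (-0.303) lay below that bound (-0.263). The median is the Ccr2 value, among 3 genes chosen because they fell, and 0.5 of the Csf1r fall (-0.46) lies within the interval. A smaller loss of macrophages is therefore not excluded. Dilution by cells without stroma is argued against by the fibroblast score, which differed by -0.087 (-0.286 to 0.111), and the endothelial score (-0.05). Without PBS mouse 26 (-0.310), 29 (-0.334) or 592 (-0.318) or CpG1826 mouse 58 (-0.329) or 183 (-0.329), though, the fibroblast score alone could not exclude 0.5 of the fall. Dilution by skin cannot be judged from these scores, because skin would bring fibroblasts and vessels of its own. A fall of these 3 transcripts within the cells may remain as one hypothesis, beside dilution by skin and a smaller loss of macrophages. A loss of a monocyte subset too small to move the abundant transcripts was not tested. The Ccr2 call was kept only without CpG1826 mouse 595 among the 10 fits that leave out 1 mouse (limma adjusted p of 0.0158 to 0.127), and with the keratinocyte covariate all 3 genes lost their calls (Cx3cr1 -0.47 from -1.21, Ccr2 -0.51 from -0.61, and Csf1r 0.23 from -0.46), in a fit whose errors the collinearity widens, so a part from epidermal RNA is not excluded.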

How the results depend on the processing

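The fit with the keratinocyte score as a covariate was chosen after the data were seen. Of the 82 named genes called, 72 kept their call and direction wherever tested among the alternatives of normalization, filter, prior, weights, probe choice and left-out mouse, and 0 reversed, except that the filter at the median level tested only 64 of the 82 and the one at the lower quartile 80; Aplnr, Atf3, Ccr2, Cenpa, Daxx, Epcam, Mcm5, Stard4, Tek and Tlr13 lost it without at least 1 mouse, given with each gene in the results. Of the 19 lists called by camera, 15 kept their call under the same alternatives. Most named genes were picked for large changes, which favours keeping a call. Of all 930 called genes, 687 (without CpG1826 mouse 183) to 762 (without CpG1826 mouse 189) were called again with 1 mouse left out. Leaving out 1 mouse at a time gave 702 to 827 changed genes, 558 to 667 higher and 121 to 209 lower (144 or fewer without PBS mouse 29, 482 or 592 or CpG1826 mouse 50 or 183), 117 to 136 changed at least 2-fold, of which 110 to 130 higher and 3 to 8 lower (3 without PBS mouse 592 or CpG1826 mouse 189), 18 to 22 lists by camera and 14 to 16 lists by score. An adjusted p under 0.01 left 471 genes, 407 higher and 64 lower, as a stricter threshold must. Lower genes numbered 364 after a further quantile normalization, 338 with the genes below the median level left out (fewer genes tested) and 121 over all probes; the cause was not tested for the first and the last. Treat with a 1.5-fold minimum, a stricter test, gave 82 genes in place of 129, 80 higher and 2 lower. Camera with an estimated correlation passed 7 lists, because correlated genes widen its null. Fry lost the calls of 6 of the 19 lists. No paired analysis was made because the titles of the 2 groups share no number. Depth has no counterpart here: without background levels, dim probes cannot be told from unexpressed ones. The keratinocyte covariate is nearly collinear with the group (r = 0.956), which widens every error. With this covariate 169 genes passed, 141 higher and 28 lower, of which 96 were among the 930 called without it. Of the genes that passed, 166 changed at least 2-fold (26 lower), as extrapolated estimates with wide errors. By camera 21 lists passed, among them 12 of the 19. Of the 82 named genes called, 20 kept their call, among them Lcn2, Il12b, Nos2, Il1a and Ccl3. Camera directions reversed (medians in parentheses) for type I and III interferon genes (-0.48), MHC class II (0.47), immediate early and stress genes (-0.24), hypoxia (-0.24), cell cycle (0.028), oxidative phosphorylation (0.14), monocyte and macrophage (0.56), T cell (0.17), endothelial (0.28) and skeletal muscle lists (0.76). Values reversed for Krt6b (-1.45), Krt5 (-0.0235), Krt14 (-0.14), Tlr13 (0.50), Gadd45a (-0.51), Adm (-0.0445), Csf1r (0.23), Ly6d (-0.77) and Epcam (-0.24), each not past the threshold; the cytokine median was -0.05 with its camera direction kept. The cause was not tested beyond the collinearity.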

Other observations

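Most genes named here lie outside the fixed lists, and all were chosen after their values were seen. They stand as single genes, since no list of their kind was tested. Slc7a11, the cystine transporter, rose by 1.59 ± 0.07 on the log2 scale (SE, limma adjusted p = 3.64e-08), Arg2, the mitochondrial arginase, by 1.6 ± 0.17 and Slc7a2, an arginine transporter, by 1.18 ± 0.16. Tarm1, a leukocyte receptor, was higher at 2.12 ± 0.16, Hcar2, the niacin receptor, at 1.85 ± 0.15, Gpr84, a receptor for medium-chain fatty acids, at 1.61 ± 0.20 and Slamf7 at 1.61 ± 0.18. Htra4, a serine protease, rose by 2.30 ± 0.21, Edn1, endothelin, by 1.42 ± 0.17, Cd69, an early activation antigen of lymphocytes, by 1.24 ± 0.13 and Il7r by 1.18 ± 0.16. The CpG1826 and PBS values of each of these genes did not overlap. Krt16 (2.51 ± 0.28), Krt6a (2.35 ± 0.31), Stfa3 (2.25 ± 0.35) and Il1f9 (1.88 ± 0.19), the first 2 of them epidermal keratins, rose beside the keratinocyte score.

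Beside Tgfb3, which is on the cytokine list (-0.68 ± 0.13), the TGF-β receptor Tgfbr2 was lower at -0.56 ± 0.08 (SE, limma adjusted p = 0.00104), Tgfbr1 at -0.53 ± 0.11 and Nrp1, a co-receptor, at -0.83 ± 0.13; TGF-β genes as a group were not tested. Cxcr3, the receptor of Cxcl9, Cxcl10 and Cxcl11, fell by 0.70 on the log2 scale while 2 of these 3 ligands rose. Tlr12 (-0.56 ± 0.07), Nlrp1b (-0.74 ± 0.12) and Rnase6 (-0.86 ± 0.14) also fell.

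A search of 309 symbol families with limma camera, chosen after the data were seen, passed 17 families, 15 upwards and 2 downwards, and 0 of them passed with an estimated correlation. The Slfn family came first: 7 of its 9 measured genes rose and 0 fell, with a median log2 fold change of 0.60 (adjusted p = 5.14e-10, and adjusted p = 0.830 with an estimated correlation). Slfn4 rose by 1.14 ± 0.10 and Slfn2 by 0.83 ± 0.11, both of them also on the list of acute phase and innate effector genes. Of 15 Ifi genes, 8 rose and 0 fell, with a median of 0.50 (adjusted p = 5.76e-08, and adjusted p = 0.852 with an estimated correlation). Of 22 Mmp genes, 6 rose and 0 fell, with a median of 0.04 (adjusted p = 0.00320, and adjusted p = 0.927 with an estimated correlation), Mmp13 at 1.34 ± 0.12, Mmp19 at 1.05 ± 0.12 and Mmp3 at 0.95 ± 0.13 (SE). Between these came the chemokine families Cxcl (6 of 13 higher) and Ccl (7 of 19), the epidermal families Krt (10 of 52, adjusted p = 1.27e-05) and Lce (4 of 19, adjusted p = 0.000279), Oas (4 of 9) and Gbp (1 of 8), and downwards the Mcm family (2 of 10 lower, median -0.19, adjusted p = 0.00238).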
